A study of Homo sapiens with 12 samples.

How the data were processed

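Total RNA from H295R cells, a human adrenocortical carcinoma line used as a model of steroid-producing cells, was measured on 12 one-colour Agilent arrays. Per the labels, cells were kept for 24 h with 9-cis retinoic acid at 25, 50 or 75 µM, a ligand of both retinoic acid and retinoid X receptors, or with the same amount of ethanol as the control. Each of the 4 groups held 3 arrays. The labels do not say whether replicates of a group were separate cultures, so the p-values measure the spread between these samples alone, and that spread may be partly technical.

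The arrays of design 014850 had been scanned and read with Agilent Feature Extraction 9.5.1.1 (protocol GE1-v5_95_Feb07). The processed signal was an intensity per the file headers, corrected for background within each array and not scaled between arrays. The value table deposited by the authors was in log2 units. It had 41093 lines, of which 41000 matched probes. On each array 99.9% of its values lay within 0.1 of the log2 processed signal after a shift by the array's 75th percentile and centring on each probe's median over the 12 arrays. The labels do not state that method. Because each probe was centred, the deposited table served only as an alternative source for the comparisons.

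The scanner files were analysed with R 4.3.3, limma 3.58.1 and the data.table package (version 1.17.8), and were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Spots marked as outliers by Feature Extraction were dropped, spots of the same probe were averaged, and the log2 processed signal was shifted by the 75th percentile of its array. A probe was tested when its signal was well above background on all 3 arrays of at least 1 group, which left 30019 of 41000 probes. Names were matched to a RefSeq table of the assembly GRCh38.p14, used for names alone: 23434 probes were named by accession, 2317 by symbol and 1043 by an older symbol, while 10943 had only the name in the scanner file and 3263 had none. Probe coordinates are those of the scanner files, on build hg17 per the file headers. Each gene was represented by its brightest tested probe, which gave 14074 genes, 5327 of them with more than 1 tested probe. The number of arrays limits the precision, and the median standard error of a log2 fold was 0.174 or 0.175 in every comparison.

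One linear model per gene with the 4 groups was fitted with limma's lmFit and eBayes on all 12 arrays, with 8 residual and 2.98 prior degrees of freedom. Each dose was compared with control and with each other dose. A moderated F-test covered the differences among the 4 groups, and a contrast gave the linear slope over dose. P-values were adjusted by Benjamini-Hochberg over the tested genes, and an adjusted p under 0.05 is what is meant by a change. The standard errors are those of limma's fit, pooled over the 4 groups. The 25 µM arrays had the widest spread, with a root mean square SD of 0.43 against 0.18 at 50 µM. Standard errors and p-values at 25 µM can therefore be too small. The fits gave 1 log2 fold per gene from 3 arrays against 3, or from fewer where a spot had been dropped: 373 values were missing among the tested genes, and HSD3B1 and P4HA2 had 2 arrays in control, ACTB 2 at 25 µM and SRXN1 2 at 75 µM. Where a probe was not well above background on any array of the lower group, the fold is given as "at least", computed against a floor: on each array of that group the higher of the probe's own value and the lowest level of any probe well above background, averaged over the 3 arrays. An "at least" fold leaves out the error of the higher group's mean and holds for this background correction alone. With the normexp background correction, such folds at 25 µM shrank for SPHKAP and AADAC and changed sign for KCND3. Where a probe was well above background on 1 or 2 arrays of the lower group, the fitted fold is given and its size is uncertain. This held for 1 control array of RARB, TAC1 and LURAP1L, 2 control arrays of HTRA3, DMGDH, CD68, HOXD1 and PLIN2, 2 arrays of ATP4A at 50 µM and 2 of CCNE2 and COL1A1 at 75 µM.

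Before the data were examined, 26 gene lists with 769 entries (743 distinct genes, 662 of them tested), the comparisons, the alternative settings and the rule for named genes were fixed. The lists were retinoic acid target genes, retinoid receptors and metabolism, LXR target genes, PPAR target genes, steroid hormone synthesis, steroidogenic regulators with ACTH or angiotensin signalling, cholesterol synthesis and uptake, DNA replication and S phase, mitosis and G2/M, cyclins with CDKs and CDK inhibitors of G1, p53 targets, the ATF4 and amino acid stress response, the unfolded protein response with ER chaperones, NRF2 and oxidative stress, heat shock, apoptosis regulators, the insulin-like growth factor axis, Wnt and beta-catenin targets, interferon-stimulated genes, NF-kB and inflammatory genes, immediate early genes, hypoxia and glycolysis, HOX genes, extracellular matrix and adhesion, reference genes, and markers of other cell types. They were written from general knowledge, not taken from these samples. Lists were tested with limma's camera, two-sided, with its preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists and the 3 doses; the difference between 75 and 25 µM was adjusted separately. Each list was also tested with an estimated correlation, on ranks, and with fry. Counts of members that rose or fell use the adjustment over all genes, and counts "adjusted over the list alone" are given beside them for the lists that passed against control and those of retinoic acid, retinoid receptor, steroid and steroid regulator genes.

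The rule named the 10 largest rises and 10 largest falls at each dose and the 5 of each between doses, among genes that passed with no overlap between groups and a signal well above background on all 3 arrays of the higher group. It added up to 4 members of each list with the smallest p at 75 µM and a fixed set of retinoid, steroid, lipid, cell cycle and reference genes, which made 159 genes. RXRG and DHRS3 were in that set and were not tested, because their probes were too dim. Members outside the rule that are named beside a small count were chosen after their values were seen.

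Slides and array positions were read from the scanner files: each of the 3 slides held 1 array of every group, and the 75 µM arrays all lay at position 2. With this design a slide block alters the spread but hardly the folds, so calls that held with it were no test of the slides. Alternatives were quantile normalization, a median shift, normexp background correction with an offset of 50, the deposited table, no filter or a stricter one on dim probes, all probes tested singly or averaged per gene, slide or replicate number as a block, array weights, an intensity trend in the prior, a fold minimum of 2, the compared groups alone, and each array left out. Normexp left out 7 spots of control replicate 1 that lay more than 100 units below their local background. Alternatives chosen after the data were seen were normexp with those spots kept, outlier spots kept, no 3 dimmest arrays, the 3 arrays of 50 µM averaged to 1, and the score of each array on the main axis of differences within groups as a covariate. Because the doses shared 3 control arrays, which cannot be divided into separate sets for the 3 doses, the overlap and correlation of doses were set against 100 simulations of unchanged groups with the same controls, and the overlap also against independent lists of the same sizes. Between 50 and 25 µM, all 3 pairs of arrays with the same replicate number had deviations with r over 0.1 (0.136, 0.257 and 0.223). The numbers were therefore taken to pair these 2 groups, from the data and not from the labels. The 3 pairs of 25 and 75 µM arrays on the same slide also had r over 0.1 (0.724, 0.26 and 0.276). Of 36 pairs with other numbers 11 did so too, so the pairing by number was not told apart from chance.

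The fits were tested on simulated data with 14074 genes per comparison, of which 67, 67 and 66 were changed by 1.5, 2 and 4-fold. For 25 µM against control, 26.9%, 65.7% and 93.9% of these were recovered with 5 false calls among 129. For 50 µM the shares were 31.3%, 77.6% and 87.9%, and for 75 µM they were 28.4%, 59.7% and 87.9%. In a simulation with 3 of the 26 lists shifted by 0.5 on the log2 scale, all 3 were found and no other list was. The simulated genes were independent of each other and had the same spread in all groups. The real groups differed in spread and had a main axis of differences within groups, so these rates may not hold for the real arrays. Some genes named by the rule above are not reported here.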

Results

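Gene expression was measured in H295R cells after 24 h with 9-cis retinoic acid at 25, 50 or 75 µM or with ethanol alone, with 3 arrays per group. The 75th percentile of the processed signal was 935.5 to 967.2 intensity units on the control arrays, 466.5 to 857.3 at 25 µM, 531.7 to 680.1 at 50 µM and 807.2 to 973.3 at 75 µM. Between 70.4% and 76.7% of the 41000 probes on each array were well above background. Levels are given as log2 signal relative to the 75th percentile of the array, and fold changes as differences of these on the log2 scale with their standard error (SE).

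The deposited design names 1 question, how the expression profile of the cells changed with each dose of the compound. Of 14074 genes tested, 8021 differed among the 4 groups by limma's moderated F-test after Benjamini-Hochberg adjustment (7618 with the slide as a block), and 6420 had a linear trend over dose, 2595 upward and 3825 downward (6248 with the slide as a block). GDF15, a secreted cytokine of cell stress, rose most of all genes at 75 µM. HMOX1, the inducible heme oxygenase, also rose at each dose, while HSD3B2, the adrenal enzyme that makes progesterone and androstenedione from their precursors, fell at each dose. The 3 arrays of 50 µM were much closer to each other than those of other groups. The root mean square SD over genes was 0.18 there, against 0.30 in control, 0.43 at 25 µM and 0.26 at 75 µM. Replicated probes of these 3 arrays differed by a median of 0.056 to 0.063, and those of other groups by 0.121 to 0.421. With the 3 arrays of 50 µM averaged to 1, a setting chosen after the data were seen, the F-test passed 3795 genes.

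**Figure D1:**
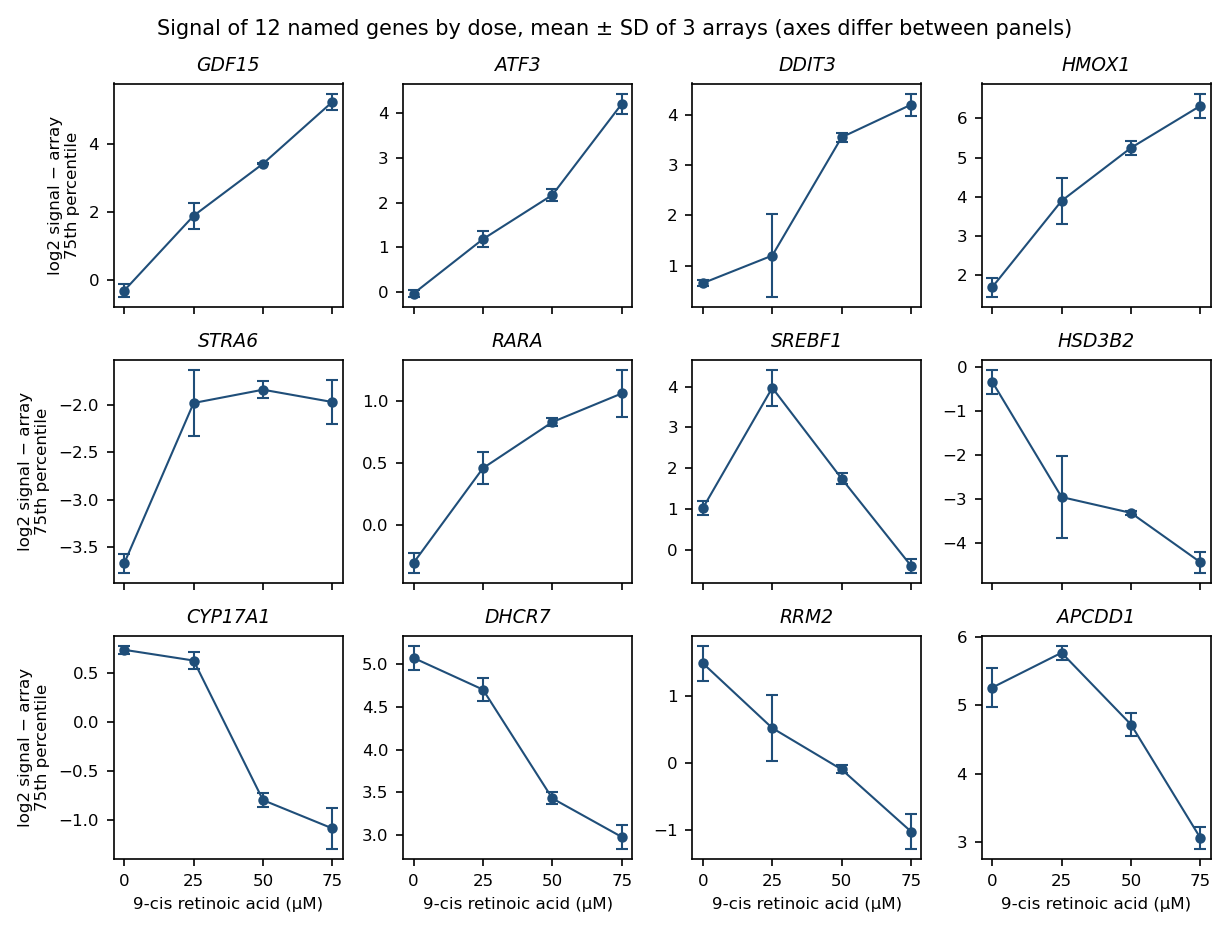
Level of 12 genes (log2 signal relative to the array's 75th percentile, vertical axes) against the dose of 9-cis retinoic acid in µM (horizontal axes), with dots for the mean and bars for the SD of 3 arrays, joined by lines. GDF15 went from -0.32 in control to 5.23 at 75 µM, and SREBF1 from 1.03 in control to 3.97 at 25 µM and -0.38 at 75 µM.

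At 25 µM against control, the largest rises were in lipid and stress genes and the largest falls included steroid synthesis genes. ABCG1, a cholesterol exporter (probe on chromosome 21 at 42589853 to 42589912, build hg17 per the file headers), rose by 3.05 ± 0.22 (SE, n = 3 arrays per group; adjusted p = 6.15e-05). SREBF1, the transcription factor that controls fatty acid synthesis genes (chromosome 17, 17656144 to 17656203), rose by 2.94 ± 0.20 (adjusted p = 6.03e-05), from a level of 1.03 ± 0.18 (SD) in control to 3.97 ± 0.44. GDF15 (chromosome 19, 18360890 to 18360949) rose by 2.21 ± 0.19 (adjusted p = 0.000127) and HMOX1 (chromosome 22, 34114676 to 34114735) by 2.20 ± 0.27 (adjusted p = 0.00111). HSD3B2 (chromosome 1, 119676714 to 119676773) fell by 2.62 ± 0.36 (adjusted p = 0.00221), from -0.34 ± 0.27 (SD) in control to -2.96 ± 0.93. STRA6, the membrane receptor for retinol uptake and a known target of retinoic acid (chromosome 15, 72259119 to 72259178), rose by 1.69 ± 0.18 (adjusted p = 0.000393).

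Other large rises at 25 µM were AKR1B10, an aldo-keto reductase that reduces retinal, at 2.28, SFRP4, a secreted Wnt antagonist, at 2.28, and EID3 at 2.12. MSC, a basic helix-loop-helix transcription factor, was at least 3.24-fold higher and COL2A1 at least 2.3-fold higher. Among the falls were ATP4A, a subunit of the gastric proton pump, at -2.34, GNRHR, the receptor of gonadotropin-releasing hormone, at -2.00, and SPINK5, a protease inhibitor, at -1.83. SPHKAP was at least 3.67-fold lower and AADAC at least 2.76-fold lower, but with normexp background correction both folds shrank, to -0.23 (adjusted p = 0.433) and -0.18 (adjusted p = 0.683). The same correction took MYH6 from -1.94 to -0.33 (adjusted p = 0.26), and KCND3, at least 1.15-fold lower without it, to 0.27.

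In the ATF4 and amino acid stress list, 14 of 34 members rose at 25 µM and none fell (22 rose and 1 fell adjusted over the list alone), and the list shifted up by a median of 0.66 (adjusted p = 1.14e-18). Examples were ALDH1L2, a mitochondrial folate enzyme, at 1.59, ATF3, a stress-induced transcription factor, at 1.22, PPP1R15A, which restarts translation after stress, at 1.21, and NUPR1 at 0.80. DDIT3, a transcription factor of terminal ER stress, was at 0.56 ± 0.31 and did not pass (adjusted p = 0.413). In the NRF2 and oxidative stress list, 13 of 29 rose and none fell (15 and 1 adjusted over the list alone), with a median of 0.59 (adjusted p = 2.84e-16). OSGIN1 was at 1.89 and SRXN1, which repairs oxidized peroxiredoxins, at 1.66. Of 26 genes of the unfolded protein response, 3 rose (3 adjusted over the list alone; adjusted p = 1.35e-05 for the list): XBP1, its transcription factor, at 0.88, the chaperone DNAJB9 at 0.83 and SEC24D, a coat protein of ER vesicles. The SEC24D log2 fold at 25 uM was 0.69, and it did not pass with the slide as a block (adjusted p = 0.0612). In the immediate early list 2 of 24 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.000789). They were the AP-1 component FOSL1 at 1.32, the phosphatase DUSP4 at 0.73 and the nuclear receptor NR4A1, chosen after its value was seen, at -0.66. The per-slide medians of these 4 lists were all above 0, from 0.07 to 0.82, and their calls held with the slide as a block and with an estimated correlation.

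Of 15 targets of the liver X receptor (LXR), which pairs with the retinoid X receptor, 5 rose at 25 µM and none fell (6 adjusted over the list alone; median 0.33, adjusted p = 3.04e-07, with slide medians of 0.19 to 0.71). Among them were ABCG1, SREBF1, the cholesterol exporter ABCA1 at 1.5 and the stearoyl-CoA desaturase SCD, chosen after its value was seen, at 1.88. The retinoic acid target list did not pass (adjusted p = 0.0517); 3 of its 23 members rose, STRA6, the myeloid transcription factor CEBPE at 1.44 and SMAD3 at 0.58, and none fell (7 rose and 4 fell adjusted over the list alone). SMAD3 was chosen after its value was seen. The list passed without control replicate 1 and without the 25 µM replicate 2. CYP26A1, the enzyme that clears retinoic acid, was at -0.07 ± 0.20 (adjusted p = 0.925), and RARB, a receptor gene that retinoic acid induces in many cells, at 1.36 ± 0.41 (adjusted p = 0.113). The control signal of RARB was well above background on 1 of 3 arrays, so the size of its folds at each dose was uncertain. In the list of retinoid receptors and metabolism (adjusted p = 0.628) 2 of 26 rose, RARA at 0.76 and the retinal dehydrogenase ALDH1A1, chosen after its value was seen, at 0.78; 3 rose adjusted over the list alone. With the mean over its probes RARA was at 0.38 (adjusted p = 0.163).

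In the steroid hormone synthesis list 4 of 22 fell and 1 rose at 25 µM (5 and 1 adjusted over the list alone; median -0.31, adjusted p = 0.00366; slide medians -0.24 to -0.17). Those that fell were HSD3B2, HSD3B1 at -2.09, PAPSS2, which makes the sulfate donor of steroid sulfation, at -1.13, and CYP11A1, the enzyme that cleaves the cholesterol side chain, at -1.09. The one that rose was AKR1C3, a reductase of androgen precursors, at 0.62; PAPSS2 and AKR1C3 were chosen after their values were seen. The sequences of HSD3B1 and HSD3B2 are so alike that their probes may not tell them apart, and with the mean over its probes HSD3B1 was at -1.27 (adjusted p = 0.116). CYP11A1 passed narrowly (adjusted p = 0.0498) and its call ended with the slide as a block (adjusted p = 0.0556). CYP17A1, the 17-hydroxylase, was at -0.11 (adjusted p = 0.719), STAR, which carries cholesterol into mitochondria, at 0.00 (adjusted p = 0.998), and CYP21A2, whose probe a pseudogene may also bind, at -0.70 (adjusted p = 0.055). Of 29 steroidogenic regulators, 3 fell and 1 rose (11 and 2 adjusted over the list alone; adjusted p = 0.00643). The corticotropin receptor MC2R fell by 1.61, and the nuclear receptors NR4A3 and NR4A1 by 1.40 and 0.66, while NR0B1, a repressor of steroid synthesis genes, rose by 1.44; of these only NR4A3 was in the rule, and the rest were chosen after their values were seen. Without the 25 µM replicate 1 that list no longer passed (adjusted p = 0.124).

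Of 29 cholesterol synthesis and uptake genes 2 fell at 25 µM (9 fell and 1 rose adjusted over the list alone; adjusted p = 0.00123), among them the esterifying enzyme SOAT1, chosen after its value was seen, at -0.63. Of 45 DNA replication genes 4 fell (6 adjusted over the list alone; adjusted p = 6.28e-06, but adjusted p = 0.0699 with an estimated correlation). They were RRM2, a subunit of the enzyme that makes deoxynucleotides, at -0.97, and GINS4, GINS2 and MCM10, replication factors chosen after their values were seen. None of 43 mitosis genes passed singly, with 0 adjusted over the list alone, although the list shifted down by a median of -0.23 (adjusted p = 5.87e-05). Its medians on slides 1, 2 and 3 were -0.17, -0.04 and -0.32, and those of DNA replication were -0.33, -0.03 and -0.27, so both shifted little on slide 2. The Wnt list shifted up (adjusted p = 0.0271), with adjusted p = 0.063 with an estimated correlation. Its 2 changed members were the receptor FZD7, at 0.84, and the antagonist SFRP1, at -0.89, both chosen after their values were seen (8 rose and 2 fell adjusted over the list alone). The call of the Wnt and beta-catenin targets list, at 25 uM, also ended on ranks (adjusted p = 0.0644), with normexp (0.307), with no filter on dim probes (0.0737), and without control replicate 3 (0.0725) or the 25 µM replicate 3 (0.227). The hypoxia and glycolysis list also shifted up (adjusted p = 0.0401), with adjusted p = 0.0699 with an estimated correlation, and 1 of 29 rose (1 adjusted over the list alone), the oxygen sensor EGLN3 at 0.68, chosen after its value was seen. The hypoxia and glycolysis list, at 25 uM, also lost its call with quantile normalization (adjusted p = 0.0526), normexp (0.631), the replicate number as a block (0.0528), no filter on dim probes (0.0943), and without control replicate 3 (0.112) or the 25 µM replicate 3 (0.265). In the interferon-stimulated genes list, at 25 uM, 2 of 31 fell (2 adjusted over the list alone; adjusted p = 0.0186), IFITM1, an antiviral membrane protein, at -0.61 and the proteasome subunit PSMB9, chosen after its value was seen, at -0.79. That list did not pass with normexp (adjusted p = 0.121) or without the 25 µM replicate 1 (adjusted p = 0.0915).

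The remaining 11 lists did not pass at 25 µM: p53 targets (5 of 29 rose, adjusted p = 0.199), heat shock (2 of 19 rose, 0.138), apoptosis regulators (2 rose and 1 fell of 38, 0.0582), extracellular matrix (1 rose and 3 fell of 32, 0.121), the insulin-like growth factor axis (2 of 19 fell, 0.413), NF-kB genes (1 of 16 fell, 0.892), PPAR targets (0 of 18, 0.786), G1 cyclins and inhibitors (0 of 21, 0.125), HOX genes (0 of 30, 0.329), reference genes (0 of 18, 0.98) and markers of other cell types (0 of 14, 0.861). For NF-kB genes the median was 0.06 and the mean -0.04, and for the retinoid receptor list -0.02 and 0.003. In all, 479 genes changed at 25 µM, 262 upward and 217 downward, and 161 of them by at least 2-fold. With the slide as a block 389 passed. The upward share of the calls, 54.7%, was 34.6% without the 25 µM replicate 3, 45.8% without replicate 1 and 39.6% with array weights. Most other settings kept an upward majority. Groups did not overlap for 15% of all genes, where chance gives 10% for independent arrays. The count moved by over 1.5 times without control replicate 2 (214) or 3 (244) and without the 25 µM replicate 1 (910), 2 (251) or 3 (1413), and normexp gave 605 genes with 70.1% upward, against 54.7%. It was 73 with only the arrays of the 2 groups fitted, which kept 14.6% of the 479 calls, so most of them depended on the variance taken from the other groups, and 78 with normexp and the stained spots kept, chosen after the data were seen.

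At 50 µM against control, lists of stress genes shifted up and those of cholesterol synthesis and DNA replication shifted down. GDF15 rose by 3.74 ± 0.19 (SE, n = 3 arrays per group; adjusted p = 7.01e-07), HMOX1 by 3.55 ± 0.27 (adjusted p = 8.51e-06) and DDIT3 by 2.91 ± 0.31 (adjusted p = 5.96e-05). HSD3B2 fell by 2.98 ± 0.36 (adjusted p = 0.000131) and CYP17A1 by 1.55 ± 0.12 (adjusted p = 8.6e-06), from 0.74 ± 0.04 (SD) in control to -0.80 ± 0.07. DHCR7, the last enzyme of cholesterol synthesis, fell by 1.63 ± 0.12 (adjusted p = 7.32e-06). MSC was at least 14.9-fold higher, and KIT, the stem cell factor receptor, at least 6.46-fold lower.

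Among other large changes at 50 µM, NGFR, a neurotrophin receptor, rose by 3.41, OSGIN1 by 3.31, DMGDH, a mitochondrial choline-pathway enzyme, by 3.13, ABCG1 by 3.04 and NIBAN1, a stress-response gene, by 3.01. TMC2 was at least 2.49-fold higher. MYH6, a cardiac myosin chain, was at least 8.05-fold lower, CACNA2D3, a calcium channel subunit, at least 6.18-fold lower and PLEKHA7, a junction protein, at least 5.93-fold lower. ATP4A fell by 3.61 and NR4A3 by 3.07. For AADAC, ADAMTS4, BANK1, C11orf87, CCK and LYZL4, which also fell among the dimmest probes, normexp left folds of -0.05 to -0.35 that did not pass.

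Of the 34 ATF4 targets 29 rose at 50 µM and 1 fell (30 and 2 adjusted over the list alone; median 1.54, adjusted p = 5.59e-19). PPP1R15A was at 2.90, ALDH1L2 at 2.89, ATF3 at 2.21 and NUPR1 at 2.20; the one that fell was VLDLR, a lipoprotein receptor chosen after its value was seen, at -0.98. In the unfolded protein response list 15 of 26 rose and none fell (16 adjusted over the list alone; median 0.68, adjusted p = 1.52e-08). HYOU1, an ER chaperone, was at 2.88, SEC24D at 1.92, DNAJB9 at 1.71 and XBP1 at 1.24. In the NRF2 list 15 of 29 rose and 2 fell (17 and 4 adjusted over the list alone; median 0.79, adjusted p = 6.02e-08). AKR1B10 was at 2.71 and SRXN1 at 2.27; those that fell were GPX1 at -0.59 and CAT at -0.54, enzymes that remove hydrogen peroxide, both chosen after their values were seen. In the immediate early list 16 of 24 rose and 3 fell (17 and 4 adjusted over the list alone; adjusted p = 8.78e-05). FOSL1 was at 2.74, DUSP4 at 1.56 and the transcription factor EGR1 at 0.63, against NR4A1 at -1.63 and the phosphatases DUSP2 at -0.76 and DUSP1 at -0.65, these 3 chosen after their values were seen. The slide medians of these lists lay between 0.46 and 1.64.

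Of 29 cholesterol genes 18 fell at 50 µM and 1 rose (20 and 1 adjusted over the list alone; median -0.79, adjusted p = 3.52e-05; slide medians -1.03 to -0.72). DHCR7 was at -1.63 and INSIG1, a sterol sensor, at -1.41; GGPS1, which makes geranylgeranyl diphosphate, rose by 0.42 and was chosen after its value was seen. Of 45 DNA replication genes 34 fell and none rose (36 adjusted over the list alone; median -0.95, adjusted p = 2.68e-09; slide medians -1 to -0.90). RRM2 was at -1.59, the helicase BLM at -1.44, thymidylate synthase TYMS at -1.38 and the polymerase clamp PCNA at -0.96. Of 43 mitosis genes 24 fell and none rose (25 adjusted over the list alone; median -0.54, adjusted p = 7.95e-05; slide medians -0.68 to -0.56), with CDK1, the mitotic kinase, at -1.18, DLGAP5 at -0.99, KIF23 at -0.97 and ASPM at -0.93. The proliferation marker MKI67 was at -0.44 and did not pass (adjusted p = 0.312). Of 15 LXR targets 10 rose and 3 fell (10 and 4 adjusted over the list alone). The list passed (adjusted p = 0.0186), but not with an estimated correlation (adjusted p = 0.122) or on ranks (adjusted p = 0.0504). PLTP, a phospholipid transfer protein, was at 1.54. The SREBF1 log2 fold at 50 uM was 0.72, and it did not pass without the 50 µM replicate 1 (adjusted p = 0.0567). The members that fell were lipoprotein lipase, LPL, at -1.42, which with normexp was at -0.20 and did not pass, the receptor gene NR1H3, chosen after its value was seen, at -1.15, and the apolipoprotein APOC1 at -1.06.

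The steroid synthesis list did not pass at 50 µM (adjusted p = 0.126), although 10 of its 22 members fell and 3 rose (10 and 3 adjusted over the list alone). HSD3B1 was at -3.16, SULT2A1, the sulfotransferase of dehydroepiandrosterone, at -1.27 and STAR at -0.69, while CYP11B1, the cortisol-forming enzyme whose probe CYP11B2 transcripts may also bind, was at -0.02 (adjusted p = 0.917). The regulators (adjusted p = 0.56) had 11 falls and 6 rises among 29 (11 and 6 adjusted over the list alone). MRAP, the accessory protein of the corticotropin receptor, was at -1.79 and GATA6 at -1.20, while NR5A1, the nuclear receptor that drives steroid synthesis genes, rose by 1.06 ± 0.27 (adjusted p = 0.00882). Retinoic acid targets split into 6 rises and 7 falls of 23 (7 and 7 adjusted over the list alone; adjusted p = 0.736), among them CEBPE at 2.15, STRA6 at 1.83, RARB at 1.56, MEIS2 at -1.37 and the orphan receptor NR2F2 at -1.02. CYP26A1 was at -0.63 (adjusted p = 0.0284), but at 0.07 with normexp. Retinoid receptors and metabolism genes had 4 rises and 5 falls of 26 (the same numbers adjusted over the list alone; adjusted p = 0.389), with RARA at 1.13 and RXRA, a retinoid X receptor, at -1.43.

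The other lists did not pass at 50 µM. They were hypoxia (8 rose and 4 fell of 29, adjusted p = 0.0844), extracellular matrix (4 and 16 of 32, 0.191), the insulin-like growth factor axis (2 and 9 of 19, 0.252), p53 targets (8 and 8 of 29, 0.318), interferon-stimulated genes (2 and 10 of 31, 0.393), heat shock (3 and 4 of 19, 0.446), apoptosis regulators (10 and 6 of 38, 0.466), Wnt targets (3 and 8 of 24, 0.786), PPAR targets (3 and 5 of 18, 0.892), HOX genes (4 and 11 of 30, 0.892), G1 cyclins and inhibitors (4 and 4 of 21, 0.983), NF-kB genes (2 and 5 of 16, 0.996), reference genes (1 and 5 of 18, 0.996) and markers of other cell types (5 and 7 of 14, 0.996). Retinoic acid, PPAR and p53 targets, apoptosis regulators, NF-kB genes and markers of other cell types had medians below 0 where camera's direction was up, with a mean above 0 for retinoic acid targets (0.01) and p53 targets (0.21). GAPDH was at 0.39 (adjusted p = 0.131); ACTB was at -0.47 (adjusted p = 0.00557), but at 0.27 with the mean over its probes. In all, 6001 genes changed, 2027 upward and 3974 downward, and 1681 of them by at least 2-fold. With the slide as a block 5758 passed. Groups did not overlap for 65.9% of all genes. Chance gives 10% for independent arrays, but more if the close arrays of 50 µM were not independent. The median fold of all genes was -0.14, and with normexp -0.01, so falls near that size depend on the background correction. With the 3 close arrays averaged to 1, the count was 1676.

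At 75 µM against control, GDF15 rose by 5.56 ± 0.19 (SE, n = 3 arrays per group; adjusted p = 1.66e-08), to a level of 5.23 ± 0.24 (SD) from -0.32 ± 0.18 in control. HMOX1 rose by 4.62 ± 0.27 (adjusted p = 4.67e-07), ATF3 (chromosome 1, 209182251 to 209182310) by 4.25 ± 0.14 (adjusted p = 1.66e-08) and HSPA6, a heat shock protein silent in most unstressed cells, by 3.33 ± 0.27 (adjusted p = 3.85e-06). HSD3B2 fell by 4.10 ± 0.36 (adjusted p = 7.41e-06), from -0.34 ± 0.27 (SD) to -4.44 ± 0.24. LRRC17, a secreted leucine-rich repeat protein (chromosome 7, 102178777 to 102178836), fell by 4.02 ± 0.12 (adjusted p = 1.29e-08). SREBF1, which had risen at 25 µM, fell by 1.41 ± 0.20 (adjusted p = 0.000234).

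Further large rises at 75 µM were TAC1, the precursor of substance P, at 4.79, LURAP1L at 4.62, CREB5, a transcription factor, at 4.46, NIBAN1 at 4.37 and HTRA3, a secreted protease, at 4.24. The sizes of 3 of these folds were uncertain, because the control signal was well above background on 1 of 3 arrays for TAC1 and LURAP1L and on 2 for HTRA3. MSC was at least 10.3-fold higher. KIT was at least 7.26-fold lower, MYH6 at least 9.05-fold, NDP, a ligand of the Wnt receptor FZD4, at least 7.59-fold, CACNA2D3 at least 7.4-fold, PLEKHA7 at least 6.69-fold, IGFBP5, a binding protein of insulin-like growth factors, at least 4.82-fold and SPHKAP at least 4.46-fold. HSD3B1 fell by 4.21.

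Stress lists were the ones that shifted up at 75 µM. Of 34 ATF4 targets 27 rose and 1, VLDLR at -2.16, fell (28 and 1 adjusted over the list alone; median 1.44, adjusted p = 4.56e-17). ALDH1L2 was at 3.68, DDIT3 at 3.56, PPP1R15A at 3.46 and NUPR1 at 2.53. Of 26 genes of the unfolded protein response 23 rose and none fell (24 and 1 adjusted over the list alone; median 1.11, adjusted p = 8.7e-13), with SEC24D at 2.84, DNAJB9 at 2.40, XBP1 at 1.82 and EDEM1, which routes misfolded proteins to degradation, at 1.5. Of 29 NRF2 targets 19 rose and 3 fell (19 and 3 adjusted over the list alone; median 0.95, adjusted p = 1.74e-08). AKR1B10 was at 3.80, OSGIN1 at 2.87 and SRXN1 at 2.80; those that fell were CAT at -0.64 and the glutathione peroxidases GPX2 at -0.83 and GPX4 at -0.44, chosen after their values were seen. Of 24 immediate early genes 18 rose and 2 fell (18 and 2 adjusted over the list alone; median 0.76, adjusted p = 2.73e-07). FOSL1 was at 3.44, DUSP4 at 1.92 and EGR1 at 1.65; DUSP2 at -1.14 and NR4A1 at -0.48 were the falls, chosen after their values were seen. In the heat shock list 11 of 19 rose and 1 fell (13 and 2 adjusted over the list alone; median 0.57, adjusted p = 1.24e-05). HSPA6, the chaperone cofactor DNAJB4 at 1.99, HSPA1A at 1.46 and CHORDC1 at 1.08 rose; the mitochondrial chaperonin HSPD1, chosen after its value was seen, fell by 0.55. The slide medians of these 5 lists lay between 0.57 and 1.55.

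Of 43 mitosis genes 31 fell at 75 µM and none rose (36 adjusted over the list alone; median -0.85, adjusted p = 5.97e-09). MKI67 was at -1.51, ASPM and the spindle motor KIF11 at -1.32 and DLGAP5 at -1.30. Of 45 DNA replication genes 34 fell and 1, the licensing factor CDC6, chosen after its value was seen, rose by 0.79 (36 and 1 adjusted over the list alone; median -0.76, adjusted p = 5.97e-09). RRM2 was at -2.52, cyclin E2, CCNE2, at -1.93 and TYMS at -1.52, while the CDK inhibitor CDKN1A rose by 1.33 ± 0.24 (adjusted p = 0.00117). Of 29 cholesterol genes 19 fell and 2 rose (20 and 2 adjusted over the list alone; median -1.04, adjusted p = 9.14e-06). INSIG1 was at -2.37, DHCR7 at -2.09 and SREBF2, the transcription factor of cholesterol genes, at -1.11; INSIG2, a second sterol sensor, at 0.72 and GGPS1 at 0.68 were the rises, chosen after their values were seen. Of 24 Wnt targets 14 fell and 1, MYC, chosen after its value was seen, rose by 0.39 (15 and 1 adjusted over the list alone; median -0.68, adjusted p = 5.07e-05). ISM1 was at -2.90, APCDD1, a Wnt antagonist and target, at -2.19, the stem cell receptor LGR5 at -1.81 and TNFRSF19 at -1.11. Of 32 extracellular matrix genes 15 fell and 1 rose (17 and 1 adjusted over the list alone; median -0.49, adjusted p = 0.0127, but adjusted p = 0.152 with an estimated correlation). COL1A1, a chain of type I collagen, was at -2.74 and the protease inhibitors TIMP3 and TIMP2 at -1.58 and -1.14; CCN2, connective tissue growth factor, was at least 3.6-fold higher. The slide medians of these 5 lists lay between -1.06 and -0.28.

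The steroid synthesis list did not pass at 75 µM (adjusted p = 0.0918), with 9 falls and 4 rises among 22 (10 and 5 adjusted over the list alone). SULT2A1 was at -2.15, CYP17A1 at -1.83, CYP11A1 at -1.54 and CYP11B1 at -0.48. The rises were aromatase, CYP19A1, at 1.12, AKR1C3 at 0.88, HSD17B3, which makes testosterone, at 0.57 and the electron donor POR at 0.55, all chosen after their values were seen. STAR was at -0.10 (adjusted p = 0.647) and CYP21A2 at -0.24 (adjusted p = 0.299). The regulators (adjusted p = 0.0943) had 13 falls and 4 rises among 29 (14 and 4 adjusted over the list alone), with MRAP at -2.79, NR4A3 at -1.85, the potassium channel KCNJ5 at -1.51 and GATA6 at -1.46; NR5A1 was at -0.23 (adjusted p = 0.525). Retinoic acid targets had 8 rises and 8 falls of 23 (8 and 9 adjusted over the list alone; adjusted p = 0.816), with RARB at 2.04, CEBPE at 1.89, STRA6 at 1.70, the binding protein CRABP2 at 0.86, MEIS2 at -1.45 and NR2F2 at -1.19. CYP26A1 was at -0.30 (adjusted p = 0.273). Retinoid receptors and metabolism genes had 5 rises and 6 falls of 26 (5 and 6 adjusted over the list alone; adjusted p = 0.892), with RARA at 1.36, FABP5 at 0.65, RBP5 at -0.81 and RXRA at -1.16; with the mean over its probes FABP5 did not pass (adjusted p = 0.258). LXR targets no longer passed (5 rose and 4 fell of 15, adjusted p = 0.787), with ABCG1 at 2.37, PLTP at 1.52, LPL at -1.85 and APOC1 at -1.39.

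The other lists did not pass at 75 µM. In the insulin-like growth factor list (3 rose and 10 fell of 19, adjusted p = 0.0923) IGF1 was at least 3.15-fold lower, FGFR1 was at -1.20, the adaptor GRB10 rose by 2.31, and IGF2, which is abundant in adrenocortical carcinoma, was at -0.25 (adjusted p = 0.169). In the hypoxia list (8 and 4 of 29, 0.0954) NDRG1 was at 1.30, PFKP at 1.02, P4HA2 at 1.01 and HK2 at 0.68. Among apoptosis regulators (11 and 5 of 38, 0.26) PMAIP1, a BH3-only gene, was at 2.01, the death receptor TNFRSF10B at 1.78, CASP10 at 1.01 and FAS at -0.71. Among p53 targets (7 and 5 of 29, 0.34), which also list GDF15 and TNFRSF10B, GADD45A was at 2.56 and PLK3 at 1.92. In the NF-kB list (6 and 4 of 16, 0.318) the chemokine CXCL8 was at least 2.35-fold higher, TNFAIP2 was at 1.09, IER3 at 0.82 and the adhesion molecule VCAM1 at -2.26. Interferon-stimulated genes (3 and 7 of 31, 0.805) had IFITM1 at -1.84, IFIT1 at -1.82, GBP1 at -1.21 and RSAD2 at -0.84. PPAR targets (4 and 3 of 18, 0.98) had the lipid droplet proteins PLIN2 at 2.10 and CIDEC at 1.12, ANGPTL4 at 1.26 and CD36 at -1.18. G1 cyclins and inhibitors (3 and 5 of 21, 0.892) had CDKN1C at -1.66, CDKN2C at -1.62 and CDKN2B at 0.87, and HOX genes (5 and 8 of 30, 0.787) had HOXA13 at -1.97, HOXB13 at -1.57, HOXD1 at 1.54 and HOXA11 at 0.89. Among reference genes (2 and 4 of 18, 0.898) TFRC was at 0.94, TBP at 0.52, B2M at -0.77 and ACTB at -0.59, and GAPDH was at -0.01 (adjusted p = 0.963). Markers of other cell types (4 and 7 of 14, 0.445) moved apart, with the macrophage markers CD68 at 1.90 and CD14 at 0.99 and the fibroblast marker DCN at -0.83; with normexp DCN did not pass (-0.31, adjusted p = 0.0866). Medians were below 0 and camera's direction up for retinoic acid targets, retinoid receptors, PPAR targets, p53 targets and apoptosis regulators, of which only the retinoid receptor list had a mean below 0 (-0.04). In all, 5538 genes changed, 2342 upward and 3196 downward, and 1955 by at least 2-fold. With the slide as a block 5364 passed. Groups did not overlap for 53.2% of all genes, where chance gives 10%. A median shift gave 5194 genes with 52.3% upward, against 42.3%, so the majority direction depended on the normalization, and normexp with the stained spots kept, chosen after the data were seen, gave 3097.

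**Figure D2:**
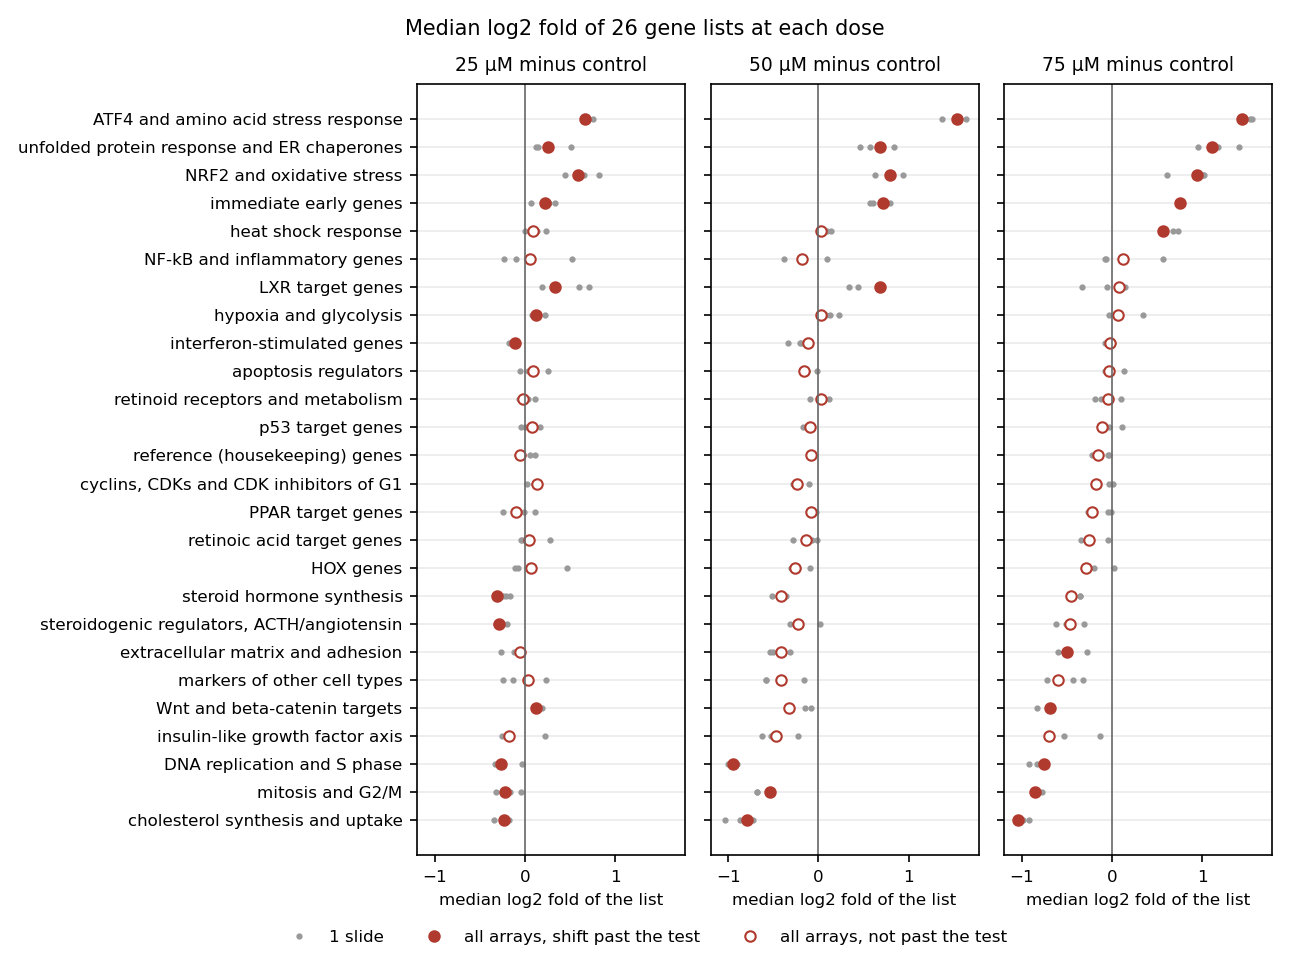
Median log2 fold of the tested members of the 26 lists (rows) against control at 25, 50 and 75 µM (panels), with grey dots for the median within 1 slide and larger symbols filled in red where camera passed and open where it did not. The ATF4 list had medians of 0.66, 1.54 and 1.44, and the mitosis list -0.23, -0.54 and -0.85.

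Between 50 and 25 µM, HYOU1 was higher at 50 µM by 2.42 ± 0.28 (SE, n = 3 arrays per group; adjusted p = 0.000456), NGFR by 2.41 ± 0.34 (adjusted p = 0.00111) and DDIT3 by 2.35 ± 0.31 (adjusted p = 0.000766). SREBF1 was lower, with a difference of -2.22 ± 0.20 (adjusted p = 0.000214), as was CYP17A1 at -1.44 (adjusted p = 0.000151). STRA6 differed by 0.14 ± 0.18 and did not pass (adjusted p = 0.523). Normexp ended the calls of DLL4, LURAP1L, ADAMTS4 and C11orf87, which the rule also named, and left KCNE1, a dim potassium channel subunit, with an opposite fold at 50 µM. In all, 5677 genes differed, 1906 upward and 3771 downward (5481 with the slide as a block). With only the arrays of these 2 groups fitted, 2701 differed, which kept 46.8% of the calls. Normexp with the stained spots kept, chosen after the data were seen, gave 1491. Groups did not overlap for 55.9% of all genes. Chance gives 10% for independent arrays, but more if the close arrays of 50 µM were not independent. The count was 2927 without the 50 µM replicate 2 and 3084 without replicate 3, 3462 with the first axis of differences between arrays of 1 group as a covariate, which kept 49.1% of the calls, and 74 with the 3 arrays of 50 µM averaged to 1, the last 2 settings chosen after the data were seen.

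Between 75 and 50 µM, for which no list was tested, TAC1 differed by 2.20 ± 0.22 (SE, n = 3 arrays per group; adjusted p = 0.000341), HSPA6 by 2.09 ± 0.27 (adjusted p = 0.00102), ATF3 by 2.04 ± 0.14 (adjusted p = 6.06e-05) and HSPA1A by 1.72 ± 0.13 (adjusted p = 0.000101). ATOH8, a transcription factor, was at least 7.08-fold lower, NDP at least 2.95-fold lower and LRRC17 lower with a difference of -2.47 ± 0.12 (adjusted p = 3.82e-06). LGR5 differed by -1.97 and APCDD1 by -1.66, and NR5A1 by -1.29 (adjusted p = 0.00796). Calls of LURAP1L and GCM1 ended when single arrays were left out, and those of CXCL8 and MBOAT4 with normexp. In all, 3530 genes differed, 2130 upward and 1400 downward (3161 with the slide as a block); a median shift gave 3787 with 72.3% upward, against 60.3%. The upward majority did not hold for the 539 genes that differed at least 2-fold, 206 upward and 333 downward, and was 51% with all probes tested singly. Groups did not overlap for 58.8% of all genes. Chance gives 10% for independent arrays, but more if the close arrays of 50 µM were not independent. The count was 1853, 1370 or 1608 without the 50 µM replicate 1, 2 or 3, 1434 or 1614 without the 75 µM replicate 2 or 3, and 31 with the 3 arrays of 50 µM averaged to 1.

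Between 75 and 25 µM, SREBF1 differed by -4.35 ± 0.20 (SE, n = 3 arrays per group; adjusted p = 4.03e-07). TAC1 was higher at 75 µM by 3.80 ± 0.22 (adjusted p = 1.26e-06), HSPA6 by 3.38 ± 0.27 (adjusted p = 7.22e-06) and GDF15 by 3.35 ± 0.19 (adjusted p = 1.08e-06). ATOH8 was at least 10.6-fold lower, NDP at least 6.13-fold and IGFBP5 at least 3.48-fold lower, and LURAP1L at least 10.9-fold higher. STRA6 differed by 0.01 ± 0.18 (adjusted p = 0.977) and CYP11A1 by -0.45 ± 0.27 (adjusted p = 0.223), and neither passed. The ATF4 list (26 of 34 higher and 1 lower, adjusted p = 2.26e-12), the unfolded protein response (21 of 26 higher, 9.39e-12), immediate early genes (12 of 24 higher and 1 lower, 6.57e-06), heat shock (12 of 19 higher, 9.25e-06) and the NRF2 list (11 of 29 higher and 1 lower, 0.00168) shifted up. Wnt targets (17 of 24 lower, 7.2e-08), mitosis (23 of 43 lower, 1.39e-06) and cholesterol genes (16 of 29 lower and 1 higher, 0.000303) shifted down.

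DNA replication also shifted down between 25 and 75 µM (25 of 45 lower and 1 higher, adjusted p = 5e-06), with adjusted p = 0.0723 with an estimated correlation. LXR targets shifted down (9 of 15 lower and 3 higher, adjusted p = 0.0114), with adjusted p = 0.107 with an estimated correlation; SREBF1, SCD at -2.06 and LPL at -1.54 were lower, and PLTP at 1.37 was higher. Extracellular matrix genes shifted down (13 of 32 lower and 3 higher, adjusted p = 0.0442), with adjusted p = 0.29 with an estimated correlation. That call also ended with no filter on dim probes, and without the 25 µM replicate 2 or 3 or the 75 µM replicate 1. The other 15 lists did not pass; among them, retinoid receptors, p53 targets and apoptosis regulators had medians below 0 where camera's direction was up. All 11 calls held with the slide as a block, which was no test of the slides. In all, 4579 genes differed, 1994 upward and 2585 downward (4376 with the slide as a block), and groups did not overlap for 38.3% of all genes, where chance gives 10%. Normexp gave 5199 genes with 33.2% upward and a median shift 4339 with 51.9% upward, against 43.5%, and normexp with the stained spots kept, chosen after the data were seen, gave 1836.

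Of the 479 genes changed at 25 µM, 221 rose and 201 fell at 50 µM as well, where independent lists of these sizes would share 37.7 and 61.3, and 3 went in opposite directions. At 75 µM 206 rose and 185 fell as well, against 43.6 and 49.3 for independent lists, and 21 went in opposite directions, SREBF1 among them. Of the genes changed at 50 µM, 59.3% changed in the same direction at 75 µM, 2322 of them downward where independent lists would share 902, and 40 went in opposite directions. Independent lists leave out the shared controls, so part of each excess may come from the 3 controls. Simulated unchanged groups with the same controls shared 0 calls on average. Unchanged groups give almost no calls, so this could not show how large that part was. The folds of 50 and 75 µM had a correlation of 0.778 across genes, which are not independent replicates, and those of 25 µM had 0.513 with 50 µM and 0.540 with 75 µM. Because the same 3 controls enter each fold, simulated unchanged groups gave correlations of 0.501, 0.501 and 0.498. The covariances were 0.408, 0.129 and 0.151, where the simulations gave 0.026.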

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

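The tests of position 2 on the genes of opposite direction, of the slide on the count at 75 µM, and of uneven exposure and of the changes at 50 µM on the axis were chosen only after the result was seen. The 21 genes below are those that changed in opposite directions at 25 and 75 µM, and they are given with the tested difference between 75 and 25 µM. SREBF1 differed by -4.35, the selenium-binding protein SELENBP1 by -3.34, the ferritin receptor SCARA5 by -3.02, the hyaluronidase CEMIP by -2.52, the desaturase FADS2 and TSPOAP1 by -2.36 each, and ID1, an inhibitor of differentiation, by -2.04. CUX2 differed by -1.87, IGDCC3 by -1.82, KRT36 by -1.78, CHN1 by -1.69, DLX4 by -1.68, TMEM37 by -1.39, LRRC49 by -1.34, FGD6 by -1.31, LMO2 by -1.24 and CACNA1G by -1.13. LHFPL2 differed by 0.76, CIDEA by 1.47, AFG3L1P by 1.71 and MMP10 by 1.84; with normexp MMP10 was at 0.105 and did not pass (adjusted p = 0.618). The Wnt list differed between the 2 doses (adjusted p = 7.2e-08 for 75 against 25 µM), with a shift up at 25 µM and down at 75 µM. The shift up did not pass with an estimated correlation (adjusted p = 0.063), on ranks (0.0644), with normexp (0.307), or without control replicate 3 (0.0725) or the 25 µM replicate 3 (0.227), so the reversal of this list was uncertain. Among 8838 probes outside RefSeq genes, tested only in the setting with all probes tested singly, 132 changed at 25 µM, 2745 at 50 µM and 2522 at 75 µM against control.

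The first pattern was the 21 genes of opposite direction. The arrays of 75 µM were the only ones at position 2 of their slides, so a position effect could give genes that part the doses. That 17 of the 21 genes also differed between 50 and 25 µM in the direction of 75 minus 25 µM decided nothing, because the genes were chosen on the same 25 µM arrays. With the 25 µM replicate 1, 2 or 3 left out, 21, 12 or 20 of the 21 were still called at 25 µM. The genes were chosen for passing on these same arrays, which favoured keeping their calls, so this could not exclude a single array. Position 2, a single array of 25 µM and a change of response with dose, which the design names, all stay open.

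The second pattern was the number of genes changed at 75 µM, which could come from position 2. Against position as the whole cause, the folds of 75 µM had r = 0.571 across genes (Spearman's rho 0.533) with the difference of 50 minus 25 µM, which involves neither the controls nor position 2. Genes are not independent replicates. Each slide held 1 array of every group, so the 5364 genes that passed with the slide as a block, where 5538 had passed without it, were no test of the slides. An addition from position 2 to single genes stays open, because the design confounds it with the dose.

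The third pattern was an axis that held 54.8% of the sum of squares between arrays of 1 group, with the widest range among arrays of 25 µM. Against the slide as its cause, slides held a share of 0.214 of its squared scores. Against uneven exposure to the compound as its only cause, the controls, which had none, spread by 0.477 of the range at 25 µM. This could not exclude uneven exposure as a part of the wider range at 25 µM, 0.748 against 0.357 in control. Against the changes at 50 µM from control being this axis, 25% of their squared folds lay on it, although 44.7% of those of 50 minus 25 µM did, so that difference could in large part be the axis. Array brightness stays open and could not be excluded: Pearson's r within groups was -0.661 (exact permutation p = 0.256, two-sided, 12 arrays) and Spearman's rho -0.483 (exact permutation p = 0.221). Only 1 relation was computed, and r was -0.589 without the 2 farthest arrays. Between groups, brightness was not tested. The 75th percentile was at most 857.3 at 25 µM and 680.1 at 50 µM, against at least 935.5 in control. An effect of brightness on the changes at these 2 doses therefore cannot be told apart from the dose.

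Other splits of the same arrays were counted for each result. For the differences among the 4 groups, 1 of 100 drawn splits, the real one, gave as many as 8021 genes, and the highest other gave 589. For the trend over dose it was 1 of 100, with 6420 genes and 2580 in the highest other. Chance could be excluded for both if the arrays of a group were separate cultures, which the labels do not say. If they shared a culture, chance differences between cultures stay open. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real and the highest other value were 479 and 1 genes at 25 µM, 6001 and 48 at 50 µM, 5538 and 0 at 75 µM, 5677 and 0 between 50 and 25 µM, 3530 and 0 between 75 and 50 µM, and 4579 and 0 between 75 and 25 µM. In each of these 1 of the 10 splits, the real one, gave as many. For lists they were 13 and 4 at 25 µM (1 of 10), 8 and 8 at 50 µM (3 of 10), 10 and 10 at 75 µM (2 of 10), and 11 and 10 between 75 and 25 µM (1 of 10). Every other split set 2 arrays of 1 group against 2 of the other, so part of their difference stayed in it. Against control, list p-values of a split were adjusted together with those of the other doses against the same mixed controls. Equal numbers of lists therefore do not show that arbitrary groups shift as many lists as the dose.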

How the results depend on the processing

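The settings with normexp and the stained spots kept, with outlier spots kept, with the axis as a covariate, without the 3 dimmest arrays and with the 3 arrays of 50 µM averaged to 1 were chosen only after the data were seen. Of the values of named genes under settings other than leaving out 1 array, 5991 kept their direction and side of the threshold, 111 lost and 82 gained a call and 9 changed sign; with 1 array left out, 3027 kept both, 109 lost and 26 gained a call. Of the list values 874 kept both, 18 lost and 44 gained a call. Of the counts 139 stayed within 1.5 times and 47 moved; with 1 array left out 72 stayed and 12 moved. The cause was not tested, except where fewer probes, arrays or a larger minimum change explain it by construction. Probes without signal well above background limit the folds, since normexp compresses dim probes. With array weights 4241 genes changed at 25 µM, 9691 at 50 µM and 8437 at 75 µM, 9130, 7716 and 8159 differed between 50 and 25, 75 and 50, and 75 and 25 µM, and 12465 among the groups. With a minimum change of 2-fold these were 161, 1681, 1955, 1035, 539, 1349 and 2549, with 2163 for the trend. With only the compared groups fitted there were 73 at 25 µM and 2701, 5986 and 2481 between the doses. With all probes tested singly there were 10677 at 50 µM, 9962 at 75 µM, 10004 between 50 and 25 µM, 8069 between 75 and 25 µM, 14128 among the groups and 11899 with a trend. With normexp and the stained spots kept there were 78, 2547, 3097, 1491, 590, 1836, 3232 and 3735. With the axis as a covariate there were 2350 at 25 µM and 3462 between 50 and 25 µM. Without the dimmest arrays, replicates 1 and 2 of 25 µM and 3 of 50 µM, 25 µM was a single array with its spread taken from other groups, and there were 231 at 25 µM, 364 between 50 and 25 µM and 2762 between 75 and 25 µM. With 50 µM averaged to 1 array there were 215 at 25 µM, 1676 at 50 µM, 74 and 31 in its differences from 25 and 75 µM, and 3795 among the groups. With fry, which does not compare a list with other genes, 18 lists passed at 50 µM, 21 at 75 µM and 21 between 75 and 25 µM. With 1 array left out the counts were 214 to 1413 at 25 µM, 4376 to 5727 at 50 µM, 4318 to 5342 at 75 µM, 2927 to 7929 between 50 and 25 µM, 1370 to 3293 between 75 and 50 µM, 3159 to 6006 between 75 and 25 µM, 5787 to 10300 among the groups and 5218 to 7388 for the trend, and lists 11 to 15 at 25 µM, 8 at 50 µM, 10 at 75 µM and 10 to 11 between 75 and 25 µM. Signs changed for ACTB at 50 µM with the mean over its probes (0.266), and with normexp for COL1A1 (0.06), IGF1 (0.201), KCND3 (0.268) and LYZL4 (0.175) at 25 µM, CYP26A1 (0.074), KCND3 (0.095) and KCNE1 (0.451) at 50 µM, and MBOAT4 between 75 and 50 µM (-0.075). Simulated correlations of unchanged groups were 0.501, 0.498 and 0.501.

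With the replicate number as a block, 309 genes changed at 25 µM. Between 50 and 25 µM, where the numbers were taken to pair the arrays, 4758 genes differed with this block and none of the 10 calls named by the rule changed. In the other comparisons the numbers were not taken as pairs. Over all 18 pairs of arrays with the same number the median r of their deviations was 0.0725, from -0.627 to 0.421. Of these 9 were above 0.1, as were 11 of the 36 pairs with other numbers.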

Other observations

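The families below were chosen after the comparisons were seen, and 30 were tested at 3 doses. Of 72 histone genes 3 fell at 25 µM, H2BC14 at -0.51, H2BC21 at -0.45 and H2BC12L at -0.42 (adjusted p = 1.62e-09 for the family, but 0.598 with an estimated correlation). At 50 µM 63 fell and 2 rose (adjusted p = 2.38e-12), and at 75 µM 61 fell and 1 rose (adjusted p = 4.25e-14), but with an estimated correlation neither passed (0.596 for both). At the highest dose H1-5, a linker histone, was at -2.55 and H2BC5 at -1.64. H1-10 rose by 0.69 at 50 µM. Whether the probes tell the histone genes apart was not tested.

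At 50 µM 30 of 45 genes with NDUF symbols fell and none rose (adjusted p = 0.00362, but 0.596 with an estimated correlation), among them NDUFB6 at -1.08 and NDUFB4 at -0.95. The 45 were subunits of respiratory complex I, 7 NDUFAF assembly factors and the non-coding NDUFV1-DT. At the same dose 34 of 78 mitochondrial ribosomal protein genes fell and 1 rose (adjusted p = 0.0267, but 0.596 with an estimated correlation), with MRPL16 at -1.41. At 75 µM 9 of 17 glutathione transferases fell and none rose (adjusted p = 0.0296, but 0.596 with that correlation), with GSTA1 at -1.16, and 14 of 36 protocadherins fell and 2 rose (adjusted p = 0.0354, but 0.596), with PCDH20 at -2.94, PCDH1 at 1.77 and PCDHB17P at 0.72. Translation initiation genes shifted up at 75 µM (10 of 52 rose and 2 fell, adjusted p = 0.0329, but 0.376 with an estimated correlation), with EIF2AK3, the kinase PERK, at 1.63, EIF5 at 1.55 and the inhibitor EIF4EBP1 at 1.27; those that fell were EIF4E2 at -0.48 and EIF4EBP2 at -0.34. Zinc finger genes shifted up at 75 µM (76 of 418 rose and 26 fell, adjusted p = 0.0157, but 0.596 with an estimated correlation). At 25 µM 8 of 36 ABC transporters rose (adjusted p = 0.0267, but 0.376 with an estimated correlation), with ABCC3 at 1.39 and ABCA6 at 1.20, and metallothioneins shifted up (adjusted p = 0.0267, but 0.596) although none of 10 passed.

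The tests in this paragraph were planned before their result was seen. A hypothesis was that the rise and fall of SREBF1 with dose goes with the fatty acid synthesis genes that it is known to control, a list of 17 genes without SCD and FADS2, whose values had been seen. At 25 µM the list shifted up (camera p = 0.00148, adjusted p = 0.00296 over the 2 tests; p = 0.00959 with an estimated correlation), with a median of 0.08 and 3 rises (7 rose and 1 fell adjusted over the list alone): ACSL3, an acyl-CoA synthetase, at 1.23, the malic enzyme ME1 at 1.00 and MID1IP1 at 0.94. From 25 to 75 µM it shifted down (camera p = 0.00449, adjusted p = 0.00449; p = 0.0164 with an estimated correlation), with 7 genes lower (7 adjusted over the list alone) and ME1, which the NRF2 list also holds, higher by 0.55. The citrate carrier SLC25A1 differed by -1.77, PNPLA3 by -1.49 and the fatty acid synthase FASN by -1.27. ME1 stayed in the list although it was 1 of the 3 rises at 25 µM, where the NRF2 list also shifted up. Its rise was therefore no separate support for the shift. Several genes did not rise and fall with SREBF1: at 75 µM, where SREBF1 was at -1.41, ME1 at 1.55, MID1IP1 at 0.75 and ACSL3 at 0.53 stayed above control, MID1IP1 did not pass against 25 µM (adjusted p = 0.413), and SLC25A1 at -0.10, PNPLA3 at -0.20 and FASN (adjusted p = 0.195) had not passed at 25 µM. The shifts of the list went with the hypothesis and these genes went against it, so it stays open.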
